A study of Mus musculus with 16 samples.

How the data were processed

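RNA was sequenced from 16 libraries of pmi28 cells, in 6 groups: uninduced myoblasts (2 libraries per line), uninduced isolated myotubes (3 per line) and induced isolated myotubes (3 per line) of a line with inducible msx2 and GFP and a line with inducible GFP only. Per the labels, cells grew in medium with 20% fetal bovine serum and were differentiated in 10% horse serum for 3 days. Myotubes were then isolated on a mesh, cultured with the cytostatic AraC and, for induction, given doxycycline at 2 µg/ml in growth medium for 24 h. The labels do not state the medium of the uninduced myotubes, so the GFP line, treated in the same way, was the control for doxycycline, medium and GFP. Libraries were made with a stranded mRNA kit from 500 ng of total RNA with 12 PCR cycles.

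The deposited values are counts, raw reads per gene, as whole numbers for 19866 entries. The submitters' processing notes name TopHat2 2.0.11, SAMtools 0.1.19, edgeR 3.6.8 and the genome build mm9, without roles or order. The counting tool, gene annotation and strand setting are not given in the sources used here. Entries without a symbol (67, 0.0601 to 0.0878% of counts) were left out, which left 19799 genes. The reference annotation used here is of another build than mm9, so no coordinates are given, and it served only for GC content and transcript length. Of the 19799 symbols 18657 matched it directly, 982 by an older symbol and 160 not at all. The most abundant gene took 0.826 to 1.26% of a library's counts. Total counts per library were 19784873 to 33092666. The GFP transgene was not analysed here.

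One edgeR 4.0.16 model (R 4.3.3, limma 3.58.1) was fitted to all 16 libraries with 1 coefficient per group. Genes were kept by filterByExpr with a minimum count of 10 (16245 genes), scaled by TMM, and tested with robust quasi-likelihood F-tests, two-sided. P-values were adjusted by Benjamini-Hochberg over all genes within each of 9 comparisons, with a threshold of 0.05. Standard errors are the log2 fold change before edgeR's shrinkage divided by the square root of F. The fold changes printed are the shrunken ones, which can differ for genes with few reads. Comparisons were induction in each line, the difference of these inductions, differentiation in each line, the difference of these differentiations, and msx2 line against GFP line in induced myotubes, uninduced myotubes and myoblasts. CPM are counts scaled to the TMM-adjusted library size. A gene with no read in a group was set against a floor of 3 counts over the group.

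The gene lists, 34 in all, were fixed beforehand: sarcomere, calcium handling, neuromuscular junction, muscle energy metabolism, respiratory chain, muscle transcription factors, progenitor factors, fusion, S phase, G2/M, cell cycle control, p53 targets, apoptosis, BMP and TGF-beta, Dlx and bone, Wnt and Notch, extracellular matrix, matrix remodelling, interferon response, inflammation, early response, cholesterol synthesis, ribosome biogenesis, atrophy and autophagy, stress responses, chromatin, and markers of adipocytes, fibroblasts, smooth muscle, endothelium, leukocytes, neural cells, chondrocytes and pluripotent cells. Some genes of the lists were not analysed here. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone. Genes at least 2-fold higher or lower in GFP-line myotubes than myoblasts were tested in the same way in msx2 induction. A library's position between myoblasts (0) and uninduced myotubes (1) of its own line was the projection of log2 CPM (prior count 2) of the other line's differentiation genes, compared by an exact two-sided permutation test.

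Genes were named by a rule. For msx2 induction it took the 10 largest rises and 10 largest falls among genes past the threshold, with a mean of at least 2 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes. For differentiation it took the 6 largest each way in the GFP line that also passed in the msx2 line, for other comparisons the 5 largest each way (interactions without the rule on overlap), for each list up to 2 risers and 2 fallers with the smallest adjusted p, and every muscle transcription factor. Some genes that the rule names are not reported here, and no others took their place. Groups, comparisons, tests, lists, this rule and the alternatives were chosen before the data were examined, except the alternatives named next as chosen afterwards and the tests and definitions that the closing paragraphs give as such.

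Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, only the compared groups, DESeq2 1.42.0, leaving out each library in turn, an estimated correlation, fry, differentiation genes at 2 log2 units or from the same line, and prior counts of 0.5 and 5. Chosen after seeing the data were leaving out both msx2-line myotube libraries numbered 2, for genes and for list members, offsets for GC content or transcript length together with the replicate block, for genes and lists, and an exact test of the positions over every change of sign of the differences between same-numbered libraries. So were 20 simulations of all libraries with the real differentiation and no change on induction.

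Whether replicate numbers pair libraries was checked on residual log2 values of 11535 genes. Within a line, uninduced and induced myotubes of the same number had correlations across genes of 0.649, 0.725 and 0.371 in the msx2 line and 0.676, 0.727 and 0.742 in the GFP line, where genes are not independent replicates. Across the lines, same-numbered myotubes also correlated, at 0.333, 0.46 and 0.489 between uninduced libraries and 0.183, 0.393 and 0.301 between induced ones. What the numbers share across the lines is not given in the labels. Myoblast libraries showed no such pairing. The fixed model has no block, and values with the block are given where the call of a named gene or list changed or where a printed count of genes or list members moved by over 1.5 times.

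The procedure was tested on simulated data with 200 changed genes among 16147, and a list of 40 other genes shifted by a smaller amount. In a comparison of 3 against 3 libraries it recovered 70.1% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold. Of 190 genes called, 16 (8.42%) had been simulated without change, and the rest were among the changed genes and the list. Changed genes were drawn from those above a low mean level, so these rates do not cover genes with the fewest reads. Genes were simulated independently, without effects shared by a library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.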

Results

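RNA sequencing read counts were given for 16 libraries of pmi28 cells, a mouse myoblast line that fuses into multinucleated myotubes. One transgenic line carried doxycycline-inducible msx2 and GFP, and the other carried inducible GFP only. Each line was sampled as uninduced myoblasts (2 libraries), as uninduced isolated myotubes (3 libraries) and as isolated myotubes given doxycycline at 2 µg/ml for 24 h (3 libraries). Total counts per library lay between 19784873 and 33092666. They were 26902203 and 28195110 in msx2-line myoblasts and 23657757 and 23896285 in GFP-line myoblasts. They were 19830622, 27113195 and 30867084 in uninduced and 21437806, 22760198 and 25746368 in induced msx2-line myotubes. In the GFP line they were 19784873, 26483909 and 33092666 in uninduced and 21066700, 22959516 and 20017852 in induced myotubes. Levels are given as CPM, read counts scaled to library size, mean ± SD over the libraries of a group. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Between 2 libraries of a group, chi-square per degree of freedom compared counts with counting noise alone, for genes with at least 20 reads. It was 1.949 in GFP-line myoblasts, 24.82 in msx2-line myoblasts and 10.5 to 31.26 in myotubes. The GFP-line myoblast libraries thus differed little beyond counting noise. Differentiation in that line and both comparisons of the lines that use myoblasts rest on them. Reads amplified by PCR are not independent molecules, so counting limits cover counting error only. The first principal component held 88.6% of the variance of the 1000 most variable genes and separated myoblasts from myotubes, and the second held 8.2% and set induced msx2-line myotubes apart.

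**Figure D1:**
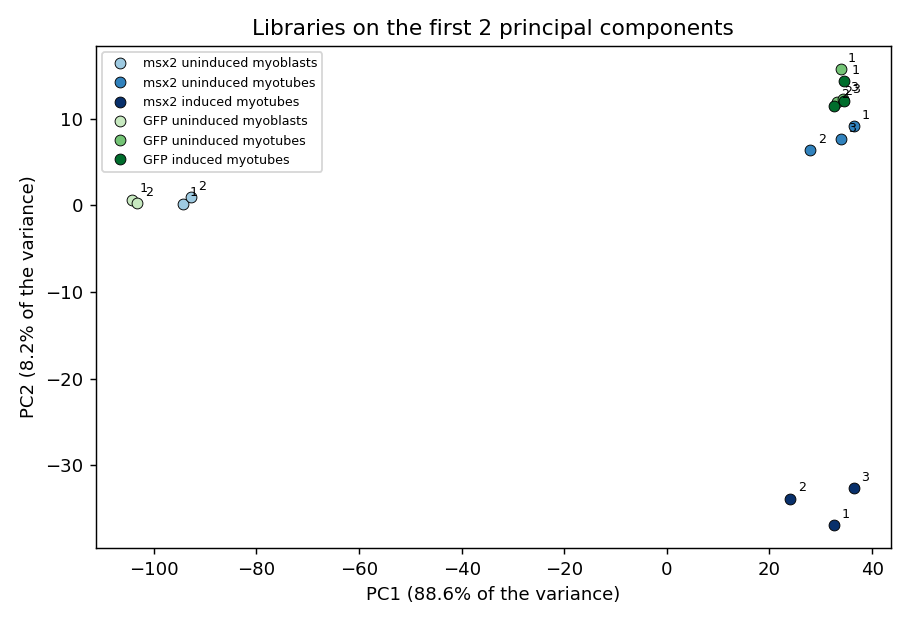
Scores of the 16 libraries on the first (x axis) and second (y axis) principal components, in arbitrary units, with replicate numbers beside the points and groups by colour. Myoblasts lie at -104.29 to -92.7 on the x axis and myotubes at 24.09 to 36.55, and the 3 induced msx2-line libraries lie at -36.97 to -32.62 on the y axis.

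Msx2, a homeobox gene for a transcriptional repressor of cell differentiation, was measured in every library first. It reached 1440 ± 87.1 CPM (SD, n = 3) in induced msx2-line myotubes and 13.7 ± 1.94 CPM (n = 3) in uninduced ones. Msx2-line myoblasts held 16.6 ± 0.277 CPM (n = 2). In the GFP line Msx2 stayed at 1.43 ± 0.219 CPM in myoblasts (n = 2), 1.11 ± 0.0723 in uninduced and 1.04 ± 0.231 CPM in induced myotubes (n = 3 each). Uninduced msx2-line cells thus held 12.3 times as much Msx2 RNA as GFP-line cells as myotubes and 11.5 times as much as myoblasts. The counts do not separate transgene reads from those of the cell's own gene. The Gfp transgene was not analysed here.

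**Figure D2:**
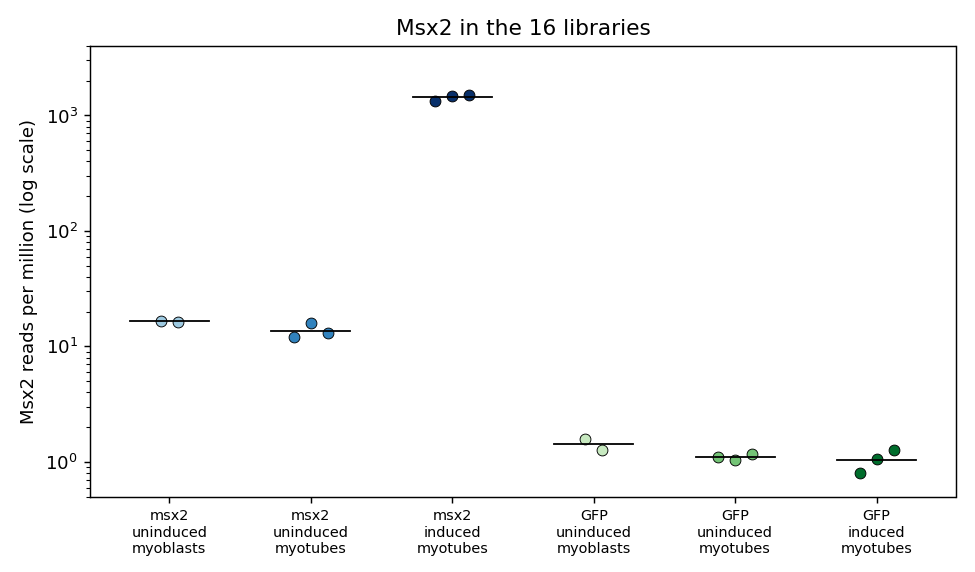
Msx2 in CPM (y axis, log scale) in each of the 16 libraries (points), by group (x axis), with a line at each group's mean. Induced msx2-line myotubes had a mean of 1440 CPM and uninduced ones 13.7 CPM, and every GFP-line group had a mean under 2 CPM.

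The central question was what msx2 expression changes in myotubes, addressed first by induced against uninduced msx2-line myotubes. The largest rises were in genes with little expression in uninduced myotubes. Muc5b, for a gel-forming mucin of mucous epithelia, rose from 0.417 ± 0.238 to 40.2 ± 18.4 CPM (log2 6.48 ± 0.47 SE, adjusted p = 1.57e-06). Muc5ac, a related mucin, rose by 5.04 ± 0.37 log2. Mybpc3, for cardiac myosin-binding protein C, rose from 0.487 ± 0.176 to 31.6 ± 5.22 CPM (n = 3 each), and Psca, for a surface antigen of prostate and stomach epithelium, rose from 0.350 ± 0.259 to 26.2 ± 4.91 CPM. Slc17a7, for the vesicular glutamate transporter of excitatory neurons, rose from 8.68 ± 0.195 to 244 ± 56.7 CPM. The other large rises were in Pth2 for a neuropeptide (5.82 ± 0.64 log2), Crhr2 for a receptor of urocortins (5.26 ± 0.40), Asb10 for an ankyrin repeat protein (5.21 ± 0.26) and Thrsp for a regulator of fatty acid synthesis (4.59 ± 0.41).

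Several of the largest falls were in genes of muscle. Fst, for follistatin, which binds activins and myostatin, fell from 215 ± 42.7 to 23.3 ± 8.33 CPM (log2 -3.20 ± 0.23, adjusted p = 3.89e-07, n = 3 each). Sln and Pln, for sarcolipin and phospholamban, both inhibitors of the calcium pump of the sarcoplasmic reticulum, had log2 changes of -3.22 ± 0.74 and -3.14 ± 0.30. Myf6, a muscle transcription factor of the MyoD family, fell from 20.2 ± 7.81 to 2.36 ± 1.17 CPM. Slc2a6 for a sugar transporter (-3.07 ± 0.31 log2), Aknad1 (-3.06 ± 0.24), Ripply1 for a corepressor active in somites (-3.06 ± 0.32) and Cldn2 for a tight junction protein (-3.05 ± 0.46) fell by similar amounts. Serpinb7 for a serine protease inhibitor (-2.93 ± 0.50) and Slc6a19 for a neutral amino acid transporter (-2.86 ± 0.20) completed the 10 largest falls.

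**Figure D3:**
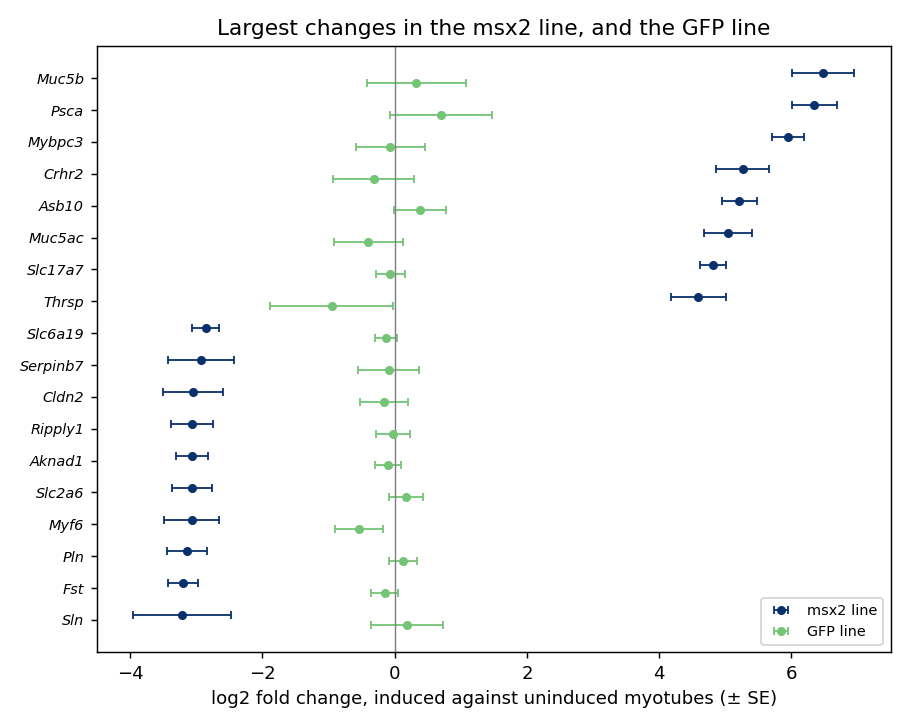
Log2 fold change (x axis) of induced against uninduced myotubes for the genes with the largest rises and falls in the msx2 line (y axis), in the msx2 line (dark) and the GFP line (light), with bars of ± 1 standard error. Msx2, shown above, is left out, as is Pth2, which had no read in a GFP-line group; the msx2-line values shown span -3.22 to 6.48.

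Of 16245 genes tested, 5287 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 2635 higher and 2652 lower with induction. At least 2-fold changes were more often rises, 748 against 440. Changes followed GC content: over 10 equal groups of genes from low to high GC, the median with the replicate block went from -0.133 to 0.176 log2. With an offset for GC content and the block, chosen after seeing the data, 6456 genes passed. Of the 6336 that passed with the block alone, 5069 (80%) kept call and direction and 1267 lost the call, and 1387 others gained it.

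Genes of the sarcomere, the contractile apparatus, fell on balance: 26 of 49 fell, 7 rose and 16 did not pass (27 and 8 adjusted over the list alone). Myh3, for embryonic myosin heavy chain, fell from 8270 ± 593 to 2080 ± 320 CPM, and Myl1, a fast myosin light chain, fell from 3200 ± 320 to 1210 ± 125 CPM. The members that rose included Myl2, the slow and ventricular light chain, from 8.85 ± 0.845 to 58.0 ± 6.35 CPM, and Mybpc2, for fast myosin-binding protein C, from 23.7 ± 5.85 to 196 ± 36.0 CPM. The list's test against all other genes gave adjusted p = 6.32e-05, and adjusted p = 0.581 with an estimated correlation. Of 24 genes of excitation-contraction coupling and calcium handling, 11 fell and 4 rose (11 and 4 adjusted over the list alone). Jph1, for junctophilin, fell by 0.99 ± 0.14 log2, while Clcn1, the muscle chloride channel, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose, Hrc by 0.62 ± 0.11. Of 12 neuromuscular junction genes, 6 fell and 2 rose (6 and 4 adjusted over the list alone, and also with the replicate block), with Musk, the agrin-activated kinase, at -1.50 ± 0.11, Chrna1, an acetylcholine receptor subunit, at -0.58 ± 0.08 and Rapsn, which clusters those receptors, at 0.67 ± 0.09 log2.

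Of 13 muscle transcription factors, 7 fell and 2 rose, the same counts adjusted over the list alone. Besides Myf6, Eya4 (-1.53 ± 0.12 log2), Mef2c (-1.31 ± 0.14), Eya1 (-1.04 ± 0.11), Smyd1, a muscle histone methyltransferase (-0.71 ± 0.11), and Myog (-0.41 ± 0.08) were among those that fell. Mef2c, which activates muscle genes with MyoD family members, fell from 1160 ± 106 to 468 ± 83.9 CPM, and Myog, for myogenin, from 774 to 583 ± 64.0 CPM. Mef2a (0.41 ± 0.09) and Six4 (0.21 ± 0.06) rose, though Six4 did not pass without replicate 2 of the uninduced myotubes (adjusted p = 0.0639) or without replicates 1 or 3 of the induced ones (0.0512 and 0.0548). Myod1 stood at 0.05 ± 0.07 log2 (278 ± 18.0 and 288 ± 16.9 CPM), and Mef2d (0.12 ± 0.08), Hopx (0.07 ± 0.19) and Tead4 (-0.14 ± 0.09) did not pass either. The list's test gave adjusted p = 0.00542, and adjusted p = 0.383 with an estimated correlation. Of 18 genes of myoblast fusion, 10 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.00584, and adjusted p = 0.383 with an estimated correlation). Jam2, a junctional adhesion molecule, fell by 1.95 ± 0.17 log2 and Myof, for myoferlin, a membrane repair and fusion protein, by 0.80 ± 0.08. Cdh15, for M-cadherin, rose by 0.48 ± 0.11 and Dock1, a Rac activator, by 0.45 ± 0.07.

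**Figure D4:**
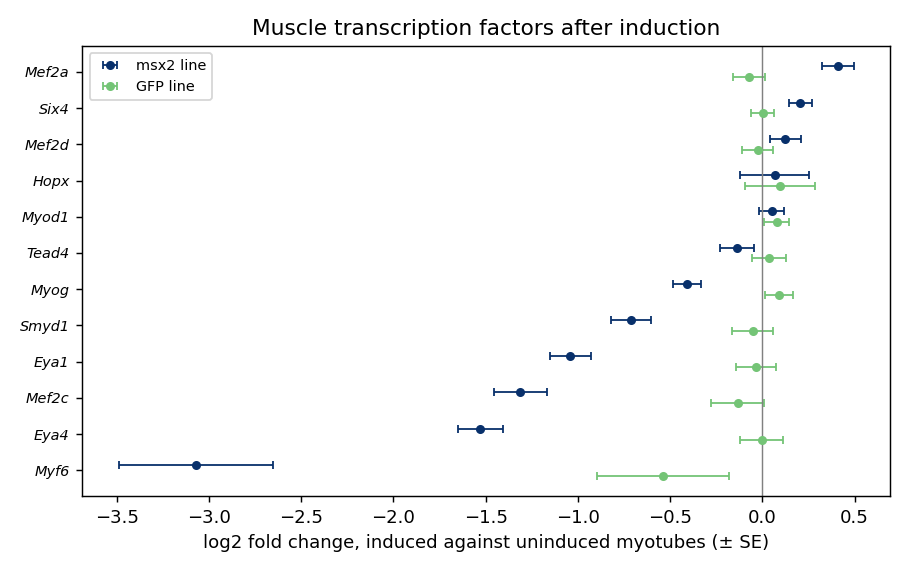
Log2 fold change (x axis) of induced against uninduced myotubes for muscle transcription factors (y axis), in the msx2 line (dark) and the GFP line (light), with bars of ± 1 standard error. In the msx2 line Myf6 lies at -3.07 and Mef2a at 0.41, and in the GFP line Myf6 lies at -0.54.

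Genes of Wnt and Notch signalling rose on balance: 15 of 31 rose and 6 fell (15 and 8 adjusted over the list alone). Heyl, a Notch target repressor, rose from 5.74 ± 0.352 to 50.3 ± 0.621 CPM, and Wnt11, a secreted ligand, from 10.4 ± 0.614 to 70.9 ± 12.7 CPM. Wif1, a secreted Wnt inhibitor (-1.68 ± 0.22 log2), and Fzd1, a Wnt receptor (-1.11 ± 0.14), fell. The test gave adjusted p = 5.3e-05, and adjusted p = 0.106 with an estimated correlation. Of 35 genes of BMP and TGF-beta signalling, 13 fell and 2 rose (13 and 4 adjusted over the list alone; 15 and 5 with the replicate block; adjusted p = 0.0113, and adjusted p = 0.383 with an estimated correlation). Tgfb2, a TGF-beta ligand, fell from 103 ± 7.45 to 44.2 ± 4.38 CPM along with Fst, while Bmp7 rose by 1.07 ± 0.28 log2. Of 28 genes of the integrated stress and unfolded protein responses, 18 fell and 3 rose (19 and 3 adjusted over the list alone; adjusted p = 0.00542, and adjusted p = 0.472 with an estimated correlation). Psat1, of serine synthesis, fell by 1.09 ± 0.10 log2 and Mthfd2, of mitochondrial folate metabolism, by 1.08 ± 0.11. Trib3, a pseudokinase induced by stress, rose by 1.53 ± 0.13 and Slc7a5, a large neutral amino acid transporter, by 0.98 ± 0.11. Of 38 chromatin genes, 15 rose and 4 fell (16 and 5 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.581 with an estimated correlation). Hdac7, a class IIa histone deacetylase, rose from 20.3 ± 5.10 to 59.9 ± 0.719 CPM and Kdm6b, an H3K27 demethylase, by 0.80 ± 0.07 log2. Suv39h1, an H3K9 methyltransferase (-0.95 ± 0.17), and Cbx5, which binds that mark (-0.53 ± 0.14), fell.

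Few genes of the S-phase and G2/M lists passed, where 32.5% of all genes did. G2/M genes had a median of -4.46 log2 in uninduced msx2-line myotubes against myoblasts, and AraC acts on cycling cells. The few calls therefore do not show that the cell cycle was unaffected. Of 52 S-phase genes, 4 rose and 5 fell (the same adjusted over the list alone; 5 and 8 with the replicate block), among them E2f2 (1.53 ± 0.10 log2) and E2f1 (1.69 ± 0.15), transcription factors of cell cycle entry, which rose, and Rrm2, a ribonucleotide reductase subunit, which fell (-1.24 ± 0.12). Of 52 G2/M genes, 1 rose and 1 fell (1 and 0 adjusted over the list alone). Of 24 cell cycle control genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone). Cdkn1c, for the inhibitor p57, rose from 4.62 ± 0.0167 to 37.7 ± 17.9 CPM, Gas6, a ligand of TAM receptors, rose by 2.85 ± 0.17 log2, and Cdk2 fell by 0.67 ± 0.10. Progenitor factors rose in 9 of 23 cases and fell in 4 (9 and 6 adjusted over the list alone). They included Sox9 (1.35 ± 0.10) among the risers and Myf5, a myoblast factor of the MyoD family, which fell (-1.98 ± 0.18).

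Of 23 genes of muscle energy metabolism, 9 rose and 4 fell (9 and 5 adjusted over the list alone). Slc2a4, the insulin-regulated glucose transporter, rose from 4.57 ± 1.04 to 33.1 ± 2.40 CPM. Of 23 atrophy and autophagy genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone), with rises in the muscle ubiquitin ligases Fbxo32 (1.05 ± 0.11 log2) and Trim63 (0.93 ± 0.07). Of 29 p53 targets, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with Eda2r, a TNF receptor family member, at -1.49 ± 0.14 log2. Of 23 matrix remodelling genes, 8 rose and 4 fell (the same adjusted over the list alone), with Mmp15, a membrane metalloproteinase, at 1.59 ± 0.10 log2 and Adamts1 at -1.12 ± 0.16. Of 39 ribosome biogenesis genes, 3 rose and 9 fell (the same adjusted over the list alone), with Rrs1 at -0.42 ± 0.09 log2. None of these 5 lists, nor progenitor factors or calcium handling, passed the test against other genes, but each passed without some library. Without replicate 1 of the uninduced myotubes, muscle energy metabolism (adjusted p = 0.00836), p53 targets (0.0449), ribosome biogenesis (0.0243) and atrophy and autophagy (0.0357) passed. Without replicate 2 of the uninduced myotubes, calcium handling (0.0363), progenitor factors (0.0363), matrix remodelling (0.0478) and atrophy and autophagy (0.0363) passed. Without induced replicate 1, progenitor factors passed (0.0302). Without induced replicate 2, muscle energy metabolism (0.036), p53 targets (0.0355) and atrophy and autophagy (0.0396) passed. Without induced replicate 3, calcium handling (0.0348) and progenitor factors (0.0339) passed. Under the replicate block and an offset for GC content, calcium handling (0.00925) and p53 targets (0.0386) passed, and with one for transcript length p53 targets and atrophy and autophagy (0.0496 each). Atrophy and autophagy also passed without both msx2-line libraries numbered 2 (0.0193). These 3 alternatives were chosen after seeing the data.

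The respiratory chain had 6 of 45 genes higher and 1 lower (4 and 0 adjusted over the list alone). It was 11 and 1 with the replicate block, and without both libraries numbered 2, chosen after seeing the data, 12 and 0. Among them was Sdha, a succinate dehydrogenase subunit (0.33 ± 0.07 log2). Of 27 apoptosis genes, 7 rose and 4 fell (the same adjusted over the list alone), Bid, a proapoptotic Bcl2 family member, rising by 1.46 ± 0.14 and Bcl2, which opposes apoptosis, falling by 0.77 ± 0.17 log2. Of 16 Dlx and bone genes, 4 rose and 4 fell (the same adjusted over the list alone); Alpl, for alkaline phosphatase of bone, rose by 1.97 ± 0.19 log2, Dlx3, a homeobox gene, rose by 1.34 ± 0.20, and Sost, a Wnt antagonist of osteocytes, fell by 2.52 ± 0.55. Of 39 extracellular matrix genes, 6 rose and 4 fell (the same adjusted over the list alone; 8 and 10 without both libraries numbered 2), Lox, a collagen cross-linking enzyme, falling from 773 ± 43.4 to 204 ± 71.1 CPM and Loxl1 rising by 1.11 ± 0.07 log2. Of 35 interferon-response genes, 4 rose and 4 fell (4 and 3 adjusted over the list alone). The counts were 7 and 5 with the replicate block, and 5 and 2 without both libraries numbered 2. Of 23 inflammation genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone), among them Il1b, for interleukin 1 beta, at -2.13 ± 0.26. Of 34 early-response genes, 8 rose and 9 fell (9 and 9 adjusted over the list alone), with Nr4a1, a nuclear receptor, at 2.19 ± 0.13 and Spry1, an inhibitor of receptor tyrosine kinase signalling, at -1.24 ± 0.11 log2. Of 24 cholesterol synthesis genes, 5 rose and 4 fell (the same adjusted over the list alone; 5 and 7 with the replicate block), with Fdft1 at 0.83 ± 0.07 log2.

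Markers of other cell types went both ways in short lists, where 32.5% of all genes passed. Of 8 adipocyte genes, 2 rose and 1 fell, with Dgat2, of triglyceride synthesis, at 2.17 ± 0.11 log2. Of 14 fibroblast genes, 3 rose and 1 fell, and Pdgfrb rose from 16.0 ± 3.98 to 50.7 ± 10.1 CPM. Of 10 smooth muscle genes, 2 rose and 2 fell, and Acta2, for smooth muscle actin, fell from 1060 ± 146 to 443 ± 196 CPM. Of 9 leukocyte genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), and Csf1r, the receptor of macrophage growth factor, rose from 0.719 ± 0.191 to 6.03 ± 0.462 CPM. Of 9 neural genes, 1 rose and 1 fell (1 and 3 adjusted over the list alone, and also with the replicate block), Nes, for nestin, which myotubes also express, rising by 0.34 ± 0.08 log2. Of 10 chondrocyte genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone), with Comp, a cartilage matrix protein, at 1.72 ± 0.27. Of 11 pluripotency genes, 1 rose and 2 fell, with Tbx3 at 1.94 ± 0.16 and Klf4 at -0.84 ± 0.14 log2. For adipocyte, fibroblast, smooth muscle and pluripotency genes the counts adjusted over the list alone were the same. None of 9 endothelial genes passed by edgeR, over all genes or adjusted over the list alone, and 1 rose with the replicate block. Median, mean and test differed in sign for 5 lists that did not pass. The G2/M list had a median of 0.09 and a mean of 0.07 with a test towards lower values. For cell cycle control (median -0.08, mean 0.21), Dlx and bone (-0.11, 0.07) and smooth muscle (-0.11, -0.10) the test pointed higher, and for early response (-0.06, 0.05) lower.

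**Figure D5:**
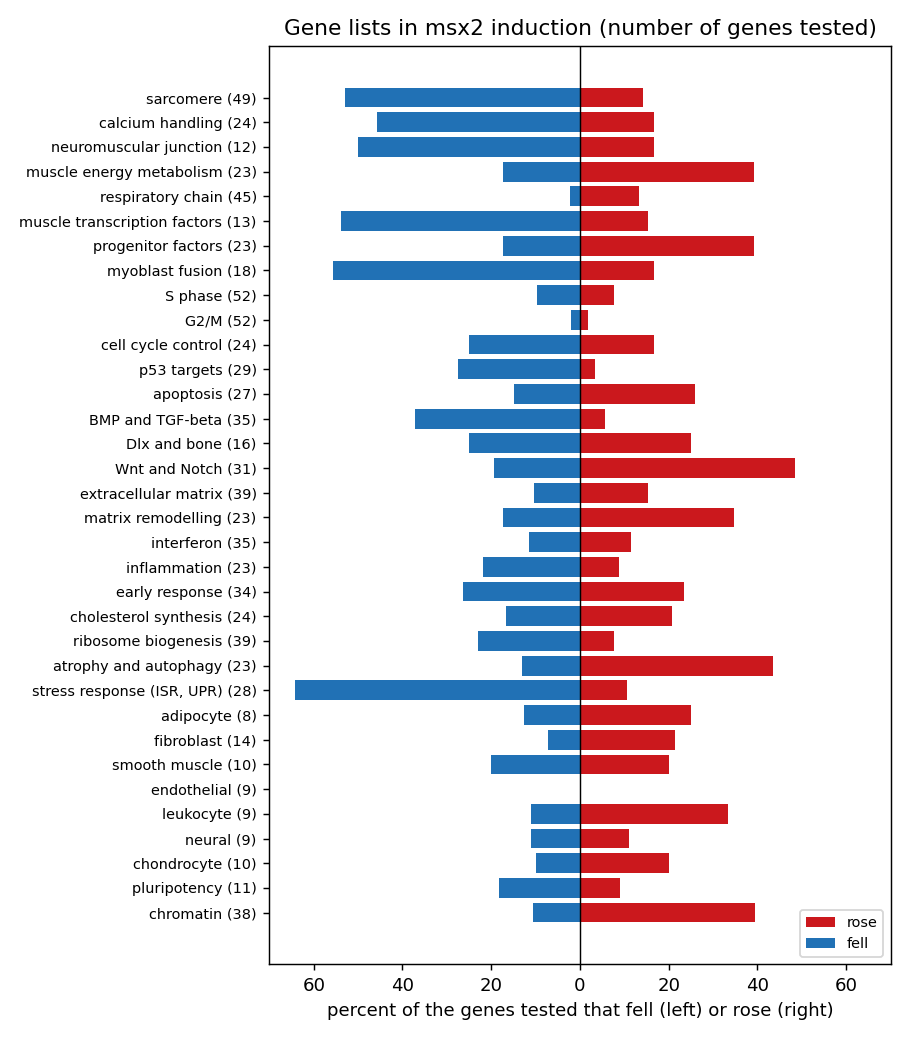
Percent of the tested genes of each of the 34 lists (y axis, number of genes tested in parentheses) that fell (left bars) or rose (right bars) on induction in msx2-line myotubes at adjusted p under 0.05. In the sarcomere list 26 of 49 genes fell and 7 rose, and in the Wnt and Notch list 15 of 31 rose and 6 fell.

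GFP-line myotubes given doxycycline in the same medium served as the control for the drug, the medium and GFP. Only 5 genes passed, all higher. Serpinb9g and Serpinb9f, for granzyme-type protease inhibitors, rose from 5.01 ± 1.37 to 24.5 ± 1.52 CPM and from 2.27 ± 0.824 to 9.92 ± 0.0898 CPM (log2 2.28 ± 0.18 and 2.08 ± 0.23). They belong to a family of near-identical copies, so their separate values are uncertain. Gpr56, an adhesion receptor of myoblast fusion, rose from 16.9 ± 2.96 to 58.5 ± 13.1 CPM, and Zfp518b, for a zinc finger protein, from 11.1 ± 0.829 to 18.5 ± 1.15 CPM. The fifth gene, AI480653 (1.60 log2), falls outside the naming rule and was chosen after its values were seen. None of the 13 muscle transcription factors passed by edgeR, the largest change being Myf6 at -0.54 ± 0.36. The respiratory chain was the only list to pass, towards lower values (adjusted p = 0.0405, and adjusted p = 0.985 with an estimated correlation), with 0 of 45 members passing by edgeR, over all genes or adjusted over the list alone.

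In this comparison 164 genes had an unadjusted p under 0.05, and DESeq2 called 10 genes. With the replicate number as a block, 17 genes and 2 lists passed, the second being muscle energy metabolism (adjusted p = 0.0243). The count was 3 without replicate 1 or without replicate 2 of the uninduced GFP-line myotubes. Zfp518b did not pass without uninduced replicate 1 (adjusted p = 0.0894) or 2 (0.0737), or without induced replicate 1 (0.0869) or 2 (0.0635). The respiratory chain did not pass without uninduced replicate 1 (0.872) or 2 (0.535) or induced replicate 3 (0.821). The list count was 2 without uninduced replicate 1, 2 without uninduced replicate 2, 5 without uninduced replicate 3, 6 without induced replicate 1 and 2 without induced replicate 2.

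The change in the msx2 line beyond that in the GFP line was tested as an interaction, and 2914 genes passed, 1487 towards a larger rise or smaller fall in the msx2 line and 1427 the other way. The interaction contains the msx2-line libraries, so it overlaps with the first comparison by construction: 2899 of its genes were also among the 5287, 2898 with the same sign. The largest differences were in Msx2 (6.81 ± 0.23 log2), Muc5b (6.15 ± 0.98), Mybpc3 (6.01 ± 0.63) and Psca (5.65 ± 1.02) in one direction. In the other they were in Sln, Pln (-3.26 ± 0.37), Slc2a6 (-3.24 ± 0.40), Fst (-3.05 ± 0.31) and Ripply1 (-3.04 ± 0.42). Heyl differed by 2.96 ± 0.12 and Myh3 by -1.96 ± 0.15. Of the muscle transcription factors, Myf6 (-2.53 ± 0.55), Eya4 (-1.53 ± 0.17), Mef2c (-1.18 ± 0.20), Eya1 (-1.01 ± 0.16), Smyd1 (-0.66 ± 0.16), Myog (-0.50 ± 0.11) and Mef2a (0.48 ± 0.12) passed, and Six4 (0.20 ± 0.09) did not. Of the 112 list examples picked in the first comparison, 92 passed here.

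Sln (-3.40 ± 0.94, adjusted p = 0.0265) did not pass without uninduced msx2-line replicate 1 (0.0598) or 3 (0.054), induced msx2-line replicate 1 (0.0601) or 2 (0.0622), uninduced GFP-line replicate 2 (0.0556) or 3 (0.0589), or induced GFP-line replicate 1 (0.0518). Pth2 passed (adjusted p = 0.0121) with no read in induced GFP-line myotubes, but not without uninduced GFP-line replicate 3 (adjusted p = 1).

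Gene lists passed in 10 cases. Sarcomere (4 higher, 21 lower of 49; adjusted p = 0.000284), fusion (1 and 8 of 18; 0.00428), muscle transcription factors (1 and 7 of 13; 0.00428), stress responses (2 and 9 of 28; 0.00428) and BMP and TGF-beta (1 and 10 of 35; 0.0246) were lower. Wnt and Notch (10 and 4 of 31; 7.62e-05), chromatin (9 and 1 of 38; 0.0187), muscle energy metabolism (7 and 1 of 23; 0.0246), progenitor factors (7 and 3 of 23; 0.0278) and atrophy and autophagy (7 and 1 of 23; 0.0473) were higher. Adjusted over the list alone, in the same order, 7 and 21, 3 and 8, 2 and 7, 2 and 12, 2 and 10, 13 and 4, 11 and 2, 8 and 1, 9 and 3, and 7 and 1 members passed. No call held with an estimated correlation, where the lowest was Wnt and Notch at adjusted p = 0.174. The sarcomere stood at adjusted p = 0.607, fusion at 0.378, muscle transcription factors at 0.378, stress responses at 0.51 and BMP and TGF-beta at 0.378, and chromatin stood at 0.607, muscle energy metabolism at 0.771, progenitor factors at 0.378 and atrophy and autophagy at 0.378. With the replicate block, calcium handling (adjusted p = 0.0382) and p53 targets (0.0427) passed too. Without uninduced msx2-line replicate 3, 6 lists passed, and BMP and TGF-beta (0.0645), progenitor factors (0.0645), muscle energy metabolism (0.0669) and atrophy and autophagy (0.0669) did not. Muscle energy metabolism also did not pass without uninduced msx2-line replicate 2 (0.0684), induced msx2-line replicate 3 (0.0575), uninduced GFP-line replicate 1 (0.113) or induced GFP-line replicate 3 (0.0682). Progenitor factors did not pass without induced msx2-line replicate 2 (0.0804). Atrophy and autophagy did not pass without induced msx2-line replicate 1 (0.0568) or 3 (0.0575), uninduced GFP-line replicate 1 (0.0908) or induced GFP-line replicate 2 (0.0506) or 3 (0.106), nor with RLE size factors (0.0509). Progenitor factors also did not pass without both msx2-line myotube libraries numbered 2, an alternative chosen after seeing the data (0.0576), and the respiratory chain did (0.0203). With the replicate block and an offset for GC content, also chosen afterwards, progenitor factors and atrophy and autophagy did not pass (0.0605 each), and calcium handling (0.00439) and p53 targets (0.0322) did. With the block alone, members higher and lower were 10 and 23 for the sarcomere, 3 and 8 for fusion, 4 and 10 for BMP and TGF-beta, 14 and 3 for chromatin, 10 and 2 for muscle energy metabolism and 8 and 4 for atrophy and autophagy. Without a library other lists passed, among them the respiratory chain, without uninduced msx2-line replicate 2 (0.0211), uninduced GFP-line replicate 3 (0.00963) or induced GFP-line replicate 1 (0.0466), and matrix remodelling, without uninduced msx2-line replicate 2 (0.0256). Ribosome biogenesis passed without uninduced msx2-line replicate 1 (0.0155), uninduced GFP-line replicate 2 (0.0236) or induced GFP-line replicate 1 (0.0214). Calcium handling passed without uninduced msx2-line replicate 2 (0.0238), induced msx2-line replicate 3 (0.0258), uninduced GFP-line replicate 1 (0.0371) or induced GFP-line replicate 2 (0.0278). The p53 targets passed without uninduced msx2-line replicate 1 (0.0434), induced msx2-line replicate 2 (0.0292) or uninduced GFP-line replicate 3 (0.0342).

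Myoblasts served as the reference for the undifferentiated state. Per the labels, myotubes had also been through a change of medium, isolation on a mesh and culture with the cytostatic AraC. Comparisons of myotubes with myoblasts, and the differentiation genes taken from them, do not separate differentiation from this handling. In the GFP line, genes of the cell cycle fell in uninduced myotubes and muscle genes rose. Ccna2, for cyclin A2, fell from 172 ± 5.59 (n = 2) to 3.16 ± 1.03 CPM (n = 3), and Mki67, a marker of cycling cells, from 421 ± 29.0 to 9.34 ± 4.73 CPM. Fam64a (-6.15 ± 0.34 log2), Aurkb, a mitotic kinase (-5.76 ± 0.31), Nuf2 of the kinetochore (-5.59 ± 0.37) and Cdca7 (-5.56 ± 0.29) fell by similar amounts. The largest rises were in genes without a read in GFP-line myoblasts, with folds set against a floor of 3 counts over the group. Cyb5r2 was at least 150-fold higher in myotubes (10.4 ± 1.75 CPM), Serpinb7 at least 122-fold, Sln at least 98.0-fold, Ptgds for prostaglandin D synthase at least 85.1-fold, Slc6a19 at least 82.1-fold and Hoxd8 at least 76.6-fold. Of 16245 genes, 12616 passed, 6460 higher and 6156 lower in myotubes.

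The msx2 line changed similarly. Fam64a (-7.26 ± 0.37 log2), Ccna2 (-6.48 ± 0.35), Aurkb (-6.41 ± 0.32), Nuf2 (-5.58 ± 0.38), Mki67 (-5.45 ± 0.51) and Cdca7 (-5.15 ± 0.27) fell, and Serpinb7, Ptgds and Cyb5r2 were at least 304-fold, 98.9-fold and 96.2-fold higher in myotubes. Slc6a19 rose by 6.22 ± 0.37. In all, 12964 genes passed, 6636 higher and 6328 lower. Of the sarcomere genes, 48 of 49 rose in the GFP line and 49 of 49 in the msx2 line, the same adjusted over the list alone (adjusted p = 0.0158 and 0.0454 with an estimated correlation, both still passing). Myom2, for myomesin 2, rose from 8.27 ± 0.813 to 1240 ± 28.4 CPM in the GFP line. Calcium handling genes rose in 23 and 24 of 24 cases, also adjusted over the list alone (adjusted p = 2.15e-28 and 1.13e-20, and adjusted p = 0.0286 and 0.0543 with an estimated correlation). Of 52 S-phase genes, 50 fell and 1 rose in the GFP line and 51 fell and 1 rose in the msx2 line, also adjusted over the list alone (adjusted p = 0.0396 and 0.0454 with an estimated correlation). All 52 G2/M genes fell in both lines, also adjusted over the list alone (adjusted p = 5.79e-29 and 2.78e-26, and adjusted p = 0.147 and 0.203 with an estimated correlation). Mef2c rose from 8.17 ± 0.783 to 1590 ± 249 CPM and Myog from 45.3 ± 2.37 to 758 ± 43.4 CPM in the GFP line, and both rose in the msx2 line (7.18 ± 0.23 and 2.28 ± 0.09 log2). Myod1 rose in the GFP line (0.54 ± 0.08) and stood at 0.09 ± 0.08 in the msx2 line. Upper-quartile scaling shifted the median change of all genes by 0.147 log2 in the GFP line and 0.216 in the msx2 line; these directions are relative to the main scaling.

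Whether msx2 induction moved myotubes back towards myoblasts was tested with genes from GFP-line differentiation, which shares no library with the induction. Of 4029 genes at least 2-fold higher in GFP-line myotubes than myoblasts, 826 fell and 651 rose on msx2 induction (median -0.085 log2), among them Myh3, Fst and Mef2c. Of 2574 genes at least 2-fold lower in myotubes, 456 rose and 367 fell (median 0.001). This second split varied: 383 and 401 without uninduced replicate 1, 538 and 269 without uninduced replicate 2, 440 and 226 without induced replicate 1, 411 and 511 without induced replicate 2 and 422 and 257 without induced replicate 3. Among genes at least 2 log2 units lower in myotubes, 122 rose and 46 fell (camera p = 0.0828 at the preset correlation). Neither set stood apart from other genes (camera p = 0.141 and 0.285, and camera p = 0.516 and 0.781 with an estimated correlation). At the preset correlation both did without replicate 2 of the uninduced msx2-line myotubes, at medians of -0.120 (camera p = 0.0127) and 0.078 (camera p = 0.0107), but not with an estimated correlation (camera p = 0.168 and 0.463). That removes the uninduced library nearest to the myoblasts on the first principal component and keeps the induced library of that number, also the nearest of its group. Without both msx2-line myotube libraries numbered 2, chosen after seeing the data, neither set passed at either correlation, at medians of -0.09 and 0. The same held with the replicate block, at medians of -0.08 and 0. In the interaction, at the preset correlation, neither set passed with all libraries, and both did without the same library, at -0.100 (camera p = 0.0204) and 0.082 (camera p = 0.00845) without it, and the lower set also passed without induced msx2-line replicate 1, at 0.052 (camera p = 0.0442). With an estimated correlation these 3 stood at camera p = 0.199, 0.452 and 0.597. The interaction contains the uninduced GFP-line myotubes that also define the sets, which works against the observed directions. In 20 simulations without any change on induction the medians averaged 0.012 and -0.010, against -0.067 and 0.004 observed. The simulations drew genes independently, without effects shared by a library. They give the direction that sharing libraries brings, and not the spread of the medians. Across genes, the changes in msx2 induction and GFP-line differentiation had a Pearson r of -0.06, where genes are not independent replicates.

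Over all differentiation genes of the GFP line, 1270 genes that fell on msx2 induction were higher in myotubes, where 1055 would be shared by independent lists. The overlap was 1011 against 1005 for genes that fell and were lower in myotubes, 1049 against 1048 for genes that rose and were higher, and 1026 against 999 for genes that rose and were lower. On a scale from myoblasts (0) to uninduced myotubes (1), induced msx2-line myotubes lay at 0.957 ± 0.044 (n = 3) and uninduced ones at 1 ± 0.042 (exact two-sided permutation p = 0.3, where 0.1 is the smallest possible). Induced GFP-line myotubes lay at 0.996 ± 0.006 (exact p = 0.6). These tests do not use the pairing by replicate number. Each induced msx2-line library lay below the uninduced one of its number, at 0.978 against 1.035, 0.906 against 0.954 and 0.987 against 1.012. An exact test on the 3 pairs, chosen after seeing the data, gave p = 0.25, the smallest it can give. In the GFP line the differences were -0.003, -0.008 and 0 after rounding, with exact p = 0.25 from unrounded values. The uninduced libraries set the value 1 of their own line, so their scatter alone places induced libraries slightly lower. The size of this shift was not measured.

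The lines were compared with each other in each state. Between induced myotubes, the msx2 line held more Mybpc3 (6.90 ± 0.27 log2), Psca (6.72 ± 0.37) and Thrsp (6.09 ± 0.51) and less Pln (-3.74 ± 0.29), Fst (-3.68 ± 0.24), Sln (-3.63 ± 0.73), Sost (-3.36 ± 0.52) and Slc2a6 (-3.36 ± 0.31). Pth2 was at least 82.8-fold higher, at 3.79 ± 1.40 CPM against no read in the GFP line. In all, 5740 genes passed, 2853 higher and 2887 lower in the msx2 line. Gene lists passed in 8 cases, none of them with an estimated correlation, where the lowest adjusted p was 0.185. Stress responses (adjusted p = 0.0328) lost the call with the replicate block (0.051). Without both msx2-line libraries numbered 2, chosen after seeing the data, progenitor factors lost the call (0.0664), and G2/M (0.0226), ribosome biogenesis (0.0438), atrophy and autophagy (0.0347) and chromatin (0.021) gained it.

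Between uninduced myotubes only 10 genes passed, Msx2 higher (3.62 ± 0.13 log2) and 9 lower in the msx2 line. Wif1 stood at 7.38 ± 2.57 against 17.5 ± 1.40 CPM in the GFP line (n = 3 each) and Dhrs7c, a muscle reductase, at 18.3 ± 1.67 against 42.0 ± 7.49 CPM. Atp13a5, of the P5 ATPases, differed by -1.11 ± 0.13 log2, Cacna1b, a neuronal calcium channel, at 5.80 ± 0.332 against 11.1 ± 1.66 and Slc43a2, an amino acid transporter, at 41.6 ± 4.67 against 63.0 ± 5.41 CPM. Calcium handling (adjusted p = 2.87e-05), G2/M (2.87e-05), muscle energy metabolism (0.00802), sarcomere (0.00815) and fusion genes (0.0149) were lower as lists. With an estimated correlation these stood at adjusted p = 0.67, 0.759, 0.759, 0.759 and 0.67. Without both msx2-line libraries numbered 2, chosen after seeing the data, muscle energy metabolism (0.135) and the sarcomere (0.437) did not pass, and the respiratory chain (0.0244) and Dlx and bone genes (0.0305) did. None of their members passed by edgeR, and adjusted over the list alone 3 calcium handling and 2 fusion genes were lower. With the block Myh7 of the sarcomere (-0.49 log2, adjusted p = 0.000252) and Cacng6 of calcium handling (-0.38, 0.0179) passed, both outside the naming rule and chosen after their values were seen. In this comparison 1584 genes had an unadjusted p under 0.05, DESeq2 called 153, and 173 passed with the replicate block (81 higher, 92 lower). The split under upper-quartile scaling was 4 higher and 11 lower. The count was 5 without msx2-line replicate 1, 2 without msx2-line replicate 2, 2 without GFP-line replicate 1 or 2 and 21 without GFP-line replicate 3. Without msx2-line replicate 1, msx2-line replicate 2, GFP-line replicate 1 and GFP-line replicate 2 in turn, Wif1 had adjusted p = 0.0775, 0.122, 0.132 and 0.148. Slc43a2 then had 0.079, 0.0944, 0.132 and 0.105, Dhrs7c 0.079, 0.121, 0.132 and 0.148 and Cacna1b 0.0919, 0.0944, 0.132 and 0.165. Without msx2-line replicate 3, Dhrs7c had 0.06 and Cacna1b 0.0965.

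Between myoblasts, muscle genes were higher in the msx2 line before any induction. Myog stood at 159 ± 7.84 against 45.3 ± 2.37 CPM (n = 2 each), Mylpf, a fast myosin light chain, at 239 ± 12.2 against 72.9 ± 1.53 CPM, and Ckm, for muscle creatine kinase, at 25.0 ± 1.61 against 6.36 ± 0.746 CPM. Tmem8c, for myomaker, a fusion protein, was 3.44-fold and Heyl 4.90-fold higher, at 33.5 ± 2.27 against 6.83 ± 0.175 CPM. R3hdml was 3.99-fold higher. Of 49 sarcomere genes, 33 were higher and 0 lower by edgeR (35 and 0 adjusted over the list alone; adjusted p = 0.0405 with an estimated correlation, still passing). Of 31 Wnt and Notch genes, 10 were higher and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 0.0405 with an estimated correlation). Of 13 muscle transcription factors 5 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.000367, and adjusted p = 0.161 with an estimated correlation). Of 52 G2/M genes, 0 were higher and 8 lower by edgeR (1 and 8 adjusted over the list alone; 1 and 11 with the replicate block; adjusted p = 0.0117, and adjusted p = 0.782 with an estimated correlation), a call lost without msx2-line replicate 2 (0.062).

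Prl2c1 (-1.90 ± 0.46 log2) and Prl2c5 (-1.63 ± 0.47), of a placental prolactin family with near-identical copies and so uncertain, Kctd12b (-1.84 ± 0.43), Tnfrsf11b, for osteoprotegerin (-1.75 ± 0.40), and Ifi205 (-1.62 ± 0.44) were lower, and Islr2 (1.98 ± 0.52) was higher. These 6 calls rest on few libraries. Without msx2-line replicate 1, adjusted p was 0.0939 for Prl2c1, 0.214 for Prl2c5, 0.1 for Kctd12b, 0.0952 for Tnfrsf11b and 0.134 for Islr2. Without msx2-line replicate 2 it was 0.0623 for Prl2c1, 0.0836 for Prl2c5, 0.0562 for Kctd12b and 0.15 for Ifi205. Without GFP-line replicate 1 it was 0.0561 for Prl2c1, 0.118 for Prl2c5, 0.0543 for Kctd12b, 0.056 for Tnfrsf11b, 0.106 for Ifi205 and 0.152 for Islr2. Without GFP-line replicate 2 it was 0.0686 for Prl2c1, 0.119 for Prl2c5, 0.0649 for Kctd12b, 0.0529 for Tnfrsf11b, 0.0932 for Ifi205 and 0.0577 for Islr2. In all, 2652 genes passed, 1476 higher and 1176 lower in the msx2 line, and under upper-quartile scaling 829 were higher and 1411 lower. The count was 764 without msx2-line replicate 1, 1156 without GFP-line replicate 1 and 853 without GFP-line replicate 2.

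Differentiation differed between the lines in 1345 genes, 651 with a larger rise or smaller fall in the msx2 line and 694 the other way. Heyl fell from 33.5 ± 2.27 to 5.74 ± 0.352 CPM in the msx2 line and stood at 6.83 ± 0.175 and 6.25 ± 0.532 CPM in the GFP line, a difference of -2.41 ± 0.13 log2. Plac8 fell by 2.68 ± 0.27 log2 in the GFP line and stood at -0.52 ± 0.27 in the msx2 line, where it did not pass, a difference of 2.16 ± 0.39. Of the 49 sarcomere genes, 29 rose less in the msx2 line and 0 more by edgeR (35 and 0 adjusted over the list alone; adjusted p = 3.57e-46, and adjusted p = 0.0524 with an estimated correlation). The comparison shares the myoblast libraries with the comparison of myoblasts, in which sarcomere genes were higher in the msx2 line. With the replicate block 2357 genes passed, 959 and 1398. The split under upper-quartile scaling was 884 and 445. The count was 454 without msx2-line myoblast replicate 1, 674 without GFP-line myoblast replicate 1 and 439 without GFP-line myoblast replicate 2.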

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

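Of the tests reported here, those with an offset for GC content or transcript length, those on levels in the higher group and that of abundant muscle genes against the share of myotubes were chosen after the result was seen.

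The inductions of the 2 lines differed in 2914 genes by the interaction test, and the differentiations in 1345. The msx2-line induction exceeded the GFP-line induction, in log2, by 6.81 for Msx2, 6.15 for Muc5b, 6.01 for Mybpc3, 5.65 for Psca, 5.58 for Crhr2, 5.55 for Thrsp, 5.44 for Muc5ac, 4.88 for Slc17a7, 4.83 for Asb10 and 0.48 for Mef2a. Pth2 passed the same test at a mean of 3.79 CPM in induced msx2-line myotubes, with no read in induced GFP-line myotubes. The difference was -3.40 for Sln, -3.26 for Pln, -3.24 for Slc2a6, -3.05 for Fst, -3.04 for Ripply1, -2.97 for Aknad1, -2.89 for Cldn2, -2.85 for Serpinb7, -2.72 for Slc6a19 and -2.53 for Myf6. It was -1.53 for Eya4, -1.18 for Mef2c, -1.01 for Eya1, -0.66 for Smyd1 and -0.50 for Myog. Of the list examples of msx2 induction, 92 passed the interaction test.

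Between the differentiations the difference, msx2 line minus GFP line, was 2.16 for Plac8, 1.99 for Col2a1, 1.97 for Ifi205, 1.87 for Vmn2r55, -2.41 for Heyl, -2.54 for Dhrs7c, -2.64 for Mfap4 and -2.68 for Chi3l1. Of these, only Plac8 and Heyl passed without each library in turn. Without msx2-line myoblast replicate 1, adjusted p was 0.0804 for Col2a1, 0.09 for Vmn2r55, 0.0987 for Chi3l1, 0.0731 for Mfap4 and 0.172 for Dhrs7c. Without msx2-line myoblast replicate 2 it was 0.0738 for Col2a1, 0.138 for Ifi205, 0.22 for Vmn2r55 and 0.136 for Chi3l1. Without GFP-line myoblast replicate 1 it was 0.0936 for Col2a1, 0.122 for Ifi205, 0.265 for Vmn2r55, 0.155 for Chi3l1, 0.0576 for Mfap4 and 0.106 for Dhrs7c. Without GFP-line myoblast replicate 2 it was 0.095 for Col2a1, 0.114 for Ifi205, 0.0865 for Vmn2r55, 0.136 for Chi3l1, 0.0745 for Mfap4 and 0.0514 for Dhrs7c. Without uninduced msx2-line myotube replicate 1 it was 0.0595 for Ifi205 and 0.064 for Vmn2r55, without replicate 2 it was 0.0542 for Ifi205, and without replicate 3 it was 0.106 for Col2a1, 0.0697 for Ifi205 and 0.0704 for Vmn2r55. Without uninduced GFP-line myotube replicate 1 it was 0.0658 for Ifi205, 0.0565 for Vmn2r55 and 0.0567 for Chi3l1, without replicate 2 it was 0.0556 for Ifi205, 0.0685 for Vmn2r55 and 0.0531 for Chi3l1, and without replicate 3 it was 0.0709 for Col2a1 and 0.0663 for Vmn2r55. With the replicate block adjusted p was 0.0778 for Col2a1, 0.0753 for Ifi205 and 0.0579 for Vmn2r55.

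In msx2 induction more genes rose than fell by at least 2-fold, 748 against 440, a ratio of 1.70, or 1.72 with the replicate block. The risers had a median GC content of 55.6% and the fallers 47.8%, against 49.9% for all genes, which goes with a GC effect on part of the excess. With an offset for GC content and the block the ratio was 1.51, which argues against GC bias as the whole cause. Of the risers 99% still passed, at any size of rise. That share decides nothing, as the offset moved no gene by more than 0.23 log2. An offset for transcript length changed 201 calls to not passing and 289 to passing over all genes, and left a ratio of 1.71. The 99.9% of risers still passing decide nothing either, as its largest shift was 0.21 log2. Over 10 groups of genes by length the medians spanned only 0.061 log2, which argues against length bias as the whole cause. Among genes at 5 CPM or more in the higher of the 2 groups, which treats rises and falls alike, the ratio with the block was 1.41, and below that 2.78. At 10 and 20 CPM or more it was 1.29 and 1.14 (counting interval 0.956 to 1.35). A measurement limit near the detection limit and a biological rise of silent genes cannot be told apart, since both place the excess among genes with few reads.

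Replicate 2 of uninduced and of induced msx2-line myotubes lay nearer to the myoblasts on the first principal component, at 27.98 and 24.09, than the other libraries of their groups. In the GFP line, replicate 2 was also the lowest of both myotube groups, at 33.2 and 32.5, but by less. In the msx2 line it had the fewest counts in 0 of the 2 groups, which argues against shallow sequencing. Cycling myoblasts left among the myotubes would bring G2/M genes and other myoblast genes in equal shares, within their spread. Relative to the other 2 libraries of its group, replicate 2 gave 0.54% (quartiles -0.02 and 1.17) from 49 G2/M genes against 3.31% (0.71 and 6.35) from 532 other genes in uninduced myotubes. In induced ones it gave 1.74% (1.22 and 3.1) against 3.82% (1.03 and 7.08), and the ratios were 0.16 and 0.46. The G2/M share thus lay between the quartiles of the other genes in induced myotubes and below them in uninduced ones. As these are deviations within a group, replicate 1 lay at -3.1% and -2.54% by the other genes. Cycling myoblasts cannot be told apart from a less mature culture here, as the bound on the ratio set beforehand for both groups was met in uninduced and not in induced myotubes, and AraC acts on cycling cells.

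Muscle genes were higher in msx2-line than in GFP-line myoblasts, among them Myog, Mylpf and Ckm. Mature myotubes among the myoblasts would need equal shares from early differentiation genes, which needed 3.84% (quartiles 0.52 and 6.49), and sarcomere genes, which needed 1.54% (0.62 and 2.9). The ratio of 2.49 fell short of the bound of 4 set beforehand, so it decides nothing. For 20 muscle genes abundant in myotubes an upper bound of the share was taken, from the most extreme myoblast libraries and the lower myotube level of the lines. By this bound 12 lay above 1.54%, though their shares may be lower, and 3 lay far below it in both libraries. These were Neb (at most 0.06%; 42.8 CPM where 113 would be needed), Mef2c (0.12%; 7.98 where 32.5 would be) and Myh4 (0.36%; 6.95 where 26.5 would be), which argues against mature myotubes as the whole cause. Low Msx2 expression without doxycycline would lower the genes that fell in msx2 induction, but these did not stand lower than other genes. Their median was 0.134 log2 against 0.078 over all genes, which upper-quartile scaling shifted by -0.06. Of these genes 36 were higher and 16 lower (camera p = 0.202 at the preset correlation and 0.747 with an estimated one). The genes that rose were higher at the preset correlation (camera p = 0.00313), though not with an estimated one (camera p = 0.097). The leak cannot be told apart from a difference between the cultures, since msx2 is carried by 1 line and each line has 2 myoblast libraries. No other biological explanation, such as cells further along differentiation, was tested.

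Splits of 3 against 3 libraries number 10, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real split gave 5287 genes and the highest other 177 in msx2 induction, 5 and 0 in GFP induction, 5740 and 0 between induced myotubes, and 10 and 0 between uninduced myotubes. For the difference between inductions 11 of 100 splits gave at least the real 2914 genes, the highest other 3591, so a grouping by chance is not excluded by this count. All 11, which include the real split, kept the msx2-line groups as they were. The others among them redrew only GFP-line libraries, and splits that redrew the msx2 line gave at most 112 genes.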

How the results depend on the processing

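Alternatives chosen after seeing the data were those without both msx2-line myotube libraries numbered 2, those with GC or length offsets and the paired test of positions; the cause was not tested for any change below unless one is named. GFP induction (5 genes) gave 17 genes with the replicate block, 3 with only the compared groups (fewer libraries), 10 with DESeq2 and 3 to 7 without a library. Uninduced myotubes between lines (10) gave 20 without a low-count filter, 173 with the replicate block, 1 with only the compared groups, 153 with DESeq2, 5 without both libraries numbered 2 (fewer libraries) and 2 to 21 without a library. Myoblasts between lines (2652) gave 5173 with only the compared groups and 764 to 2152 without a library, where the lone library left in a group is assumed to vary like the other groups. The difference between differentiations (1345) gave 2357 with the replicate block and 439 to 1642 without a library. Counts without a library stayed within 1.5 times for msx2 induction (4417 to 5227), the difference between inductions (2445 to 3084), msx2-line (11880 to 12799) and GFP-line differentiation (11345 to 12257) and induced myotubes between lines (4907 to 5503). With the replicate block these 5 counts were 6336, 4005, 13156, 12797 and 6626, and myoblasts gave 3864. Besides the calls given elsewhere in this text, the block added the extracellular matrix list in msx2-line differentiation (adjusted p = 0.0492) and progenitor factors in GFP-line differentiation (0.0243), and it changed no other call of a list or of a gene named in this text. With the block and an offset for GC content, the difference between inductions gave 4009 genes, and 82.1% of those with the block alone kept call and direction. With an offset for transcript length 96.8% did so there and in msx2 induction. Lists passing with the block and these offsets numbered 9 and 9 for msx2 induction and 10 and 12 for the difference between inductions. Without both libraries numbered 2, the extracellular matrix (0.00313) and early-response lists (0.0431) gained the call in msx2-line differentiation, and the extracellular matrix (0.00986) and matrix remodelling lists (0.0372) in the difference between differentiations.

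With an estimated correlation, lists passing were 0 for msx2 induction (7), 0 for GFP induction (1), 0 for the difference between inductions (10), 2 for msx2-line (15) and 3 for GFP-line differentiation (13) and 2 for myoblasts (13). Fry, which does not compare a list with other genes, gave 18 for msx2 induction, 0 for GFP induction, 31 for msx2-line and 28 for GFP-line differentiation. For GFP induction upper-quartile scaling gave 0 lists, the replicate block 2 and single libraries left out 0 to 6. Without a library, lists numbered 7 to 11 for msx2 induction and 6 to 12 for the difference between inductions. The G2/M list in GFP induction reversed without GFP uninduced myotube replicate 1, to a median of 0.24 (adjusted p = 3.77e-09), in a range from -0.23. Medians of genes higher in myotubes ranged from -0.12 to -0.061 in msx2 induction and from -0.1 to -0.036 in the difference between inductions without a library, and of genes lower in myotubes from -0.07 to 0.078 and from -0.065 to 0.082.

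Of 7894 values of named genes under alternatives 7581 kept direction and side of the threshold, 306 lost the threshold (242 without a library), 7 newly passed and 0 reversed. Besides, 58 values below the threshold in both settings changed sign and count as unchanged. Of these, 27 were of named genes, 14 of gene lists and 17 of differentiation sets. Depth limits genes with few reads: a gene without a read in a group has only a bound on its fold.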

Other observations

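The definition of when the test below leaves its question open was made stricter after the GFP-line values were seen.

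The entry of Myo3a, for a myosin of sensory hair cells, took 0.97 to 1.26% of the counts of each myotube library. It took 0.387 to 0.511% of each myoblast library, and was the most abundant entry in most myotube libraries. The counting tool, gene annotation and strand setting are not given, so whether these reads come from Myo3a transcripts cannot be told. Heyl, a Notch target, was 4.90-fold higher in msx2-line than GFP-line myoblasts and also rose on msx2 induction in myotubes.

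Low Msx2 expression without doxycycline may act like a weak induction in uninduced myotubes. The genes that rose at least 2-fold in msx2 induction were higher as a set in uninduced msx2-line than GFP-line myotubes (camera p = 0.0181), and those that fell were lower (camera p = 0.00118), with camera p = 0.175 and 0.42 with an estimated correlation. At the preset correlation, the set that fell was also lower in GFP induction (camera p = 0.00953), which involves no Msx2, and the set that rose gave camera p = 0.0858 there. With an estimated correlation these gave camera p = 0.516 and 0.311. The uninduced msx2-line libraries also served to choose the sets, which works against the observed directions. Both tests share the uninduced GFP-line libraries, so a weak induction and a shift of these libraries cannot be told apart.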
